A study of Streptomyces clavuligerus with 20 samples.

How the data were processed

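The series holds 20 samples of Streptomyces clavuligerus mycelium: 8 RNA-seq and 8 ribosome profiling libraries, 2 per growth phase and assay, and 4 dRNA-seq libraries made from cells of several phases pooled, 2 of them treated to open the 5' ends of primary transcripts and 2 untreated. The labels of the pooled libraries numbered 1 list a cell sample of every phase, while those numbered 2 list the transition sample a second time and no late-exponential sample. For ribosome profiling the cells were treated with 20 µM thiostrepton. The assay, phase and cell sample of each library were taken from the labels.

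The main input was the table of raw counts per gene and library that the authors deposited for each assay, on locus tags of the form CRV15_. The aligner, the genome build, the counting program, the handling of reads that match more than 1 gene and the strand rule are not given in the sources used here. A second table of the same libraries, deposited by the authors on RefSeq locus tags, holds raw counts, normalised signal values, log2 fold changes and a p-value per gene. Its normalised signal is the raw count divided by 1 size factor per library, and per the file headers the first table carries the mean signal of a phase after DESeq2 normalisation. Those means equalled values recomputed with DESeq2 size factors, with a largest relative difference of 1.21e-09. The deposited log2 fold changes give the later over the earlier phase, and the deposited p-value is headed as such with no word on adjustment. The submitters' processing notes name DESeq2. The authors' list of start sites gives a position, a strand, a class letter and a score per site, and the deposited score carries the sign of the strand, with a scaling not given in the sources used here. The class letters are printed as deposited.

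Of 7076 genes in the count table, 6678 had an entry in the RefSeq annotation of assembly ASM551946v1 (5321 on the chromosome, 1357 on the plasmid) and 398 had none. Only 789 had a gene symbol and no product names came with them, so gene lists rest on symbols and cover only part of each process. The table held 0 rRNA or tRNA genes, 6607 protein-coding genes and 71 pseudogenes. Genes without a symbol are named by their tag.

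Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, and libraries were scaled by TMM. The quasi-likelihood test with robust dispersion was run on all phases of an assay together, and p-values were adjusted by Benjamini-Hochberg within each comparison. An adjusted p under 0.05 was taken as a call. A standard error was computed as the absolute log2 fold change over the square root of the F statistic. The biological coefficient of variation was 0.146 in RNA-seq, 0.128 in ribosome profiling and 0.136 over all 16 libraries. The compared pairs were each later phase against early-exponential phase, late-exponential against transition and stationary against late-exponential phase. Changes in translation efficiency were tested as the interaction of assay and phase over the 16 libraries. Gene lists were tested with camera in limma 3.58.1, on 19 lists per comparison with at least 5 tested genes, with an inter-gene correlation preset at 0.01 and adjusted over those lists, and again with the correlation estimated for each list.

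Start sites were joined to the gene named with them. For sites of class P and S alone, the distance to the annotated start codon was taken within 500 nt upstream. A distance under 9 nt was called leaderless. Translation efficiency of a gene was the log2 ratio of its footprint CPM to its RNA CPM, both scaled by TMM over the 16 libraries together and with a small count added, so it differs from the ratio of the printed CPM, which are scaled by TMM within each assay. Tables and permutation tests were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, DESeq2 1.42.0 served for the alternatives, and figures were drawn with matplotlib 3.10.9.

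Before the data were examined, the tests, filters, lists, the region rule for the beta-lactam genes and the alternatives were fixed. The genes to be named were set by a rule as well: the 8 highest and 8 lowest calls with a symbol and at least 10 CPM per comparison against early-exponential phase, up to 2 each way per list, all members of the beta-lactam lists and region, and 3 each way between later phases. The text gives a part of them, and genes outside the rule are said to be chosen after their values were seen. The alternatives were DESeq2 size factors, library size alone, the DESeq2 Wald test, limma-voom for translation efficiency, no count filter, a fold of at least 2, only the 2 phases compared, a replicate block, and leaving out each library in turn. In the last, the lone library of a phase was taken to vary like the other groups. List members were found by symbol alone, which was settled after the annotation was seen and before any test. A recount on the RefSeq tags, a longer beta-lactam region, lists by symbol family, camera with library size alone, tests of leaderless genes by phase and of their RNA level, counts of genes with opposite changes under other scalings and an exact permutation test of the plasmid share were added after the data were seen.

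The cell sample pairs the RNA-seq and ribosome profiling libraries, since the labels give the same cell sample to both. This was checked in the counts, in genes with a mean of at least 10 CPM over all libraries. Deviations from the group mean correlated across these genes at -0.02 in early-exponential, 0.11 in transition, 0.10 in late-exponential and 0.29 in stationary phase. RNA-seq and ribosome profiling libraries of different phases gave -0.09 to 0.17, so only the value in stationary phase lay above those of unrelated pairs. The fits were tested on simulated data in which changes were added to counts drawn from negative binomial models of these libraries. At a log2 change of 1, 63.3% of added RNA changes were found from early-exponential to stationary phase, and 89.7% at a log2 change of 2, with 16 false calls among 165. For translation efficiency the shares were 38.0% and 89.9%, with 4 false calls among 131. In RNA the false calls were a larger share than the 0.05 aimed at. Only 195 of 6434 genes were changed in RNA and 199 of 6115 for translation efficiency, balanced in direction. The simulations therefore did not test the scaling where most genes change. The permutation test for leaderless genes gave p under 0.05 in 27 of 400 simulated sets without a difference, after 10 in the first 100, and in 100 of 100 with a log2 difference of 0.5.

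Raw reads, and with them footprint length, codon position and read coverage along genes, were not analysed here. The dRNA-seq libraries entered only through the deposited list of sites.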

Results

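Streptomyces clavuligerus, a mycelial soil bacterium known as a producer of clavulanic acid and cephamycin C, was grown in shaken liquid culture at 30 °C and collected in early-exponential, transition, late-exponential and stationary phase. For each phase 2 RNA-seq libraries and 2 ribosome profiling libraries were deposited, 16 in all. The labels tie the RNA and ribosome profiling library of a number to one cell sample. Ribosome profiling sequences the mRNA pieces that ribosomes protect, called footprints here. The ratio of footprints to RNA reads of a gene is its translation efficiency. A further 4 libraries of pooled phases came from dRNA-seq, which enriches primary transcripts to find transcription start sites. Going by the series title, the questions are how RNA and translation change over growth and which start sites and untranslated regions the genome uses.

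The RNA-seq libraries held 4641314 to 8953699 counts each and the ribosome profiling libraries 4785845 to 11576733. At these totals a count of 3 corresponds to 0.335 to 0.646 CPM (counts scaled to the same library total, here and in the correlation below without the TMM factors that the CPM of named genes include) of RNA and to 0.259 to 0.627 CPM of footprints, and such limits cover counting error only. The 50 genes with most counts took 23.6 to 27.3% of the RNA counts and 25.8 to 28.5% of the footprints. Between the libraries of a phase, Pearson r of log2 CPM was 0.976 to 0.994 across the 4697 genes with a mean of at least 10 CPM over all libraries. Over these genes each pair differed by more than sampling noise, with a chi-square of 9.76 to 48.7 per degree of freedom, and every library was counted as a replicate. Weaker genes were not part of this check. Since the labels do not say that the libraries of a phase come from separate cultures, p-values measure only the spread between these samples, which may be technical.

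From early-exponential to transition phase, the largest RNA increases among genes with a symbol were in the phosphate transporter genes pstA, pstS, pstC and pstB, which encode the high-affinity uptake system of phosphate starvation. Their log2 fold changes were 6.76 ± 0.18, 6.58 ± 0.23, 6.56 ± 0.19 and 6.30 ± 0.21 (SE, n = 2 libraries per phase). RNA of pstS (CRV15_12645, chromosome 3025652 to 3026782) went from 50.3 ± 12.3 to 4820 ± 139 CPM (SD, n = 2). Other strong increases were in asnB, an asparagine synthase gene (5.20 ± 0.38), secD of the protein export machinery (4.44 ± 0.27), eboE (4.26 ± 0.52) and hisN, a histidinol-phosphatase gene (4.26 ± 0.17). Genes that fell far included hutU (-5.08 ± 0.24) and hutH (-4.39 ± 0.21) of histidine degradation, hppD (-5.07 ± 0.37) and hmgA (-4.51 ± 0.28) of tyrosine degradation, and the 5-oxoprolinase gene pxpB (-5.27 ± 0.61).

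Lists of protein synthesis, the TCA cycle, cytochrome oxidases and ATP synthase fell in RNA at the same time, while the NADH dehydrogenase list did not. Of 51 ribosomal protein genes 47 fell and 0 rose, also when adjusted over the list alone, with rplP at -1.84 ± 0.18 and rpmC at -1.75 ± 0.22 (camera adjusted p = 1.19e-12; adjusted p = 0.421 with an estimated correlation). Of 11 translation factor genes 9 fell, 9 adjusted over the list alone, among them tsf (-1.97 ± 0.14) and efp (-1.55 ± 0.15; camera adjusted p = 0.00138; adjusted p = 0.443 with an estimated correlation). Of 20 aminoacyl-tRNA synthetase genes 15 fell, 16 adjusted over the list alone, with trpS (CRV15_09675) at -1.85 ± 0.17 and thrS at -1.43 ± 0.15 (camera adjusted p = 0.000237; adjusted p = 0.376 with an estimated correlation). All 6 TCA cycle genes fell, 6 adjusted over the list alone, including sdhA (-2.20 ± 0.18) and sucD (-2.17 ± 0.16; camera adjusted p = 0.000177; adjusted p = 0.334 with an estimated correlation). Of 9 cytochrome oxidase genes 8 fell and 1 rose, the same adjusted over the list alone, with cydB of the bd oxidase lowest at -4.81 ± 0.77 (camera adjusted p = 0.000177; adjusted p = 0.334 with an estimated correlation). The 4 ATP synthase genes fell, 4 adjusted over the list alone, led by atpB (-2.19 ± 0.15) and atpE (-2.11 ± 0.19), a list too short for the set test.

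All 6 genes of the arginine biosynthesis list fell as well, 6 adjusted over the list alone, such as argJ (CRV15_07545, -2.38 ± 0.16) and argH (-2.10 ± 0.18; camera adjusted p = 0.000237; adjusted p = 0.334 with an estimated correlation). This argJ, at 1901590 to 1902771, is the first gene after cs1, the end of the beta-lactam region described below, and CRV15_24250 is a second argJ elsewhere on the chromosome (5739739 to 5740890). Both are in the list by symbol alone, so whether CRV15_07545 serves arginine synthesis was not settled, here or in the phases below. Of 13 heat shock and proteolysis genes 10 fell, 10 adjusted over the list alone, with the chaperonin genes groL (-2.01 ± 0.19) and groES (-1.93 ± 0.22; camera adjusted p = 0.000177; adjusted p = 0.345 with an estimated correlation). Of 21 cell division and cell wall genes 13 fell and 3 rose, the same adjusted over the list alone, with mraY of peptidoglycan synthesis at -2.30 ± 0.15 (camera adjusted p = 0.00565; adjusted p = 0.334 with an estimated correlation). The phosphate starvation list rose in all 6 members, 6 adjusted over the list alone, with a median log2 fold change of 6.43 (camera adjusted p = 3.57e-06; adjusted p = 0.334 with an estimated correlation). The glutamine synthetase gene glnA (-2.73 ± 0.18), the nickel superoxide dismutase gene sodN (-2.56 ± 0.20), the thiol peroxidase gene tpx (-1.66 ± 0.16) and the enolase gene eno (-1.71 ± 0.16) fell. Pyruvate kinase RNA (pyk, CRV15_22320, 1.74 ± 0.17) and glycerol kinase RNA (glpK, CRV15_25075, 2.48 ± 0.26) rose. Among genes of development and pigments, wblA, a WhiB-like regulator, rose (1.29 ± 0.15), as did the phenoxazinone synthase gene phsA (1.63 ± 0.16). The developmental repressor gene bldD (-0.90 ± 0.14), the sporulation gene ssgD (-2.64 ± 0.43) and the tyrosinase cofactor gene melC1 (-3.37 ± 0.30) fell.

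Several lists did not pass the set test in transition phase RNA. Of 7 glycolysis genes 5 fell and 1 rose, 5 and 2 adjusted over the list alone (camera adjusted p = 0.239). Of 11 oxidative stress genes 5 fell, 5 adjusted over the list alone (camera adjusted p = 0.0859). Of 9 DNA replication genes 4 fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 0.547). Of 6 development genes 3 fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 0.8).

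Over all genes, 4011 of 6567 tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1977 higher and 2034 lower (49.3% higher). Scaled by library size alone, the split was 2650 higher and 1329 lower (66.6% higher). The median of all genes shifted by 0.36 on the log2 scale, so that directions hold relative to the TMM scaling.

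In late-exponential phase, RNA of the phosphate transporter remained far above early-exponential levels, with pstA at 6.48 ± 0.18 (log2 fold change, SE, n = 2 per phase). The genes asnB (5.14 ± 0.38), hisN (4.61 ± 0.17) and pgfA (4.22 ± 0.28) also rose. Against early-exponential phase, hutU (-5.52 ± 0.25) and hutH (-4.77 ± 0.23) fell, as did dapA of lysine synthesis (CRV15_22730, -4.96 ± 0.39), the pyruvate phosphate dikinase gene ppdK (-4.18 ± 0.20), the ectoine hydroxylase gene thpD (-4.11 ± 0.17) and cydD of the cytochrome oxidase list (-3.89 ± 0.61). Of the regulators of development, wblA rose (1.79 ± 0.15) and ssgD fell (-3.40 ± 0.49). The ribosome hibernation factor gene hpf rose (0.94 ± 0.22, adjusted p = 0.00276).

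Here 41 of the 51 ribosomal protein genes fell and 0 rose, 42 adjusted over the list alone, with rpsB at -1.39 ± 0.15 (camera adjusted p = 1.42e-07; adjusted p = 0.639 with an estimated correlation). Of 20 aminoacyl-tRNA synthetase genes 16 fell and 2 rose, the same adjusted over the list alone. The copies of trpS parted, CRV15_09675 at -1.93 ± 0.17 and CRV15_16695 at 1.02 ± 0.23 (camera adjusted p = 0.000791 for the list; adjusted p = 0.453 with an estimated correlation). Of 9 cytochrome oxidase genes 8 fell, 8 adjusted over the list alone (camera adjusted p = 0.000138; adjusted p = 0.359 with an estimated correlation). The 6 TCA cycle genes all fell, 6 adjusted over the list alone, with sdhC at -2.63 ± 0.16 (camera adjusted p = 0.00022; adjusted p = 0.359 with an estimated correlation). The 6 arginine genes also fell, 6 adjusted over the list alone, led by argJ (CRV15_07545, -2.41 ± 0.16; camera adjusted p = 0.00074; adjusted p = 0.359 with an estimated correlation). Translation factors fell in 7 of 11 members, 7 adjusted over the list alone, with tsf at -1.71 ± 0.14 (camera adjusted p = 0.0414, 0.0779 with library size alone; adjusted p = 0.727 with an estimated correlation). Of the heat shock genes 8 of 13 fell, 8 adjusted over the list alone, among them the disaggregase gene clpB (-1.74 ± 0.15; camera adjusted p = 0.00212; adjusted p = 0.453 with an estimated correlation). RNA of atpB (-2.17 ± 0.15), mraY (-2.41 ± 0.16) and melC1 (-3.67 ± 0.33) fell too. In all, 4101 of 6567 genes passed the test, 2021 higher and 2080 lower. With library size alone 2425 were higher and 1599 lower (60.3% against 49.3% higher, median shift 0.26).

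In stationary phase the phosphate list again rose in 6 of 6 members, 6 adjusted over the list alone (median 6.55; camera adjusted p = 2.3e-05; adjusted p = 0.382 with an estimated correlation), with pstA at 6.97 ± 0.18 (SE, n = 2 per phase). The pyrroloquinoline quinone precursor gene pqqA rose by 4.16 ± 0.34, asnB by 5.39 ± 0.38 and hisN by 4.89 ± 0.17 on the log2 scale. Wide falls against early-exponential phase were seen in hutU (-5.83 ± 0.25), dapA (CRV15_22730, -5.52 ± 0.37), melC1 (-5.29 ± 0.35) and ppdK (-5.03 ± 0.21). The development genes ssgD (-4.02 ± 0.47) and bldD (-1.49 ± 0.14) fell and wblA rose (1.60 ± 0.15). Of the nitrogen genes, glnA fell (-2.70 ± 0.18) while gltB of glutamate synthase rose (1.39 ± 0.28). Apart from these, RNA of a gene named fxlM rose (1.34 ± 0.13), a symbol that both CRV15_06635 and CRV15_16190 carry.

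Ribosomal protein genes fell in 44 of 51 cases, 44 adjusted over the list alone, with rplX at -1.93 ± 0.18 (camera adjusted p = 3.91e-10; adjusted p = 0.576 with an estimated correlation). Aminoacyl-tRNA synthetase genes fell in 16 of 20 cases and rose in 3, the same adjusted over the list alone, with hisS at -2.04 ± 0.15 (camera adjusted p = 0.00188; adjusted p = 0.555 with an estimated correlation). Translation factors fell in 8 of 11 cases, 8 adjusted over the list alone, tsf at -1.93 ± 0.14 (camera adjusted p = 0.014; adjusted p = 0.664 with an estimated correlation). TCA cycle genes fell in 6 of 6 cases, 6 adjusted over the list alone, with sucD at -2.71 ± 0.17 (camera adjusted p = 0.00032; adjusted p = 0.382 with an estimated correlation). Cytochrome oxidase genes fell in 8 of 9 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.00032; adjusted p = 0.382 with an estimated correlation). Heat shock genes fell in 11 of 13 cases, 11 adjusted over the list alone, with htpG at -2.29 ± 0.14 (camera adjusted p = 0.000622; adjusted p = 0.481 with an estimated correlation). Arginine genes fell in only 3 of 6 cases, 3 adjusted over the list alone, argJ (CRV15_07545) at -1.62 ± 0.16 and argF at -1.16 ± 0.17, and the list did not pass the set test (camera adjusted p = 0.591). RNA of atpB fell (-2.41 ± 0.15). In total 4413 of 6567 genes passed, 2191 higher and 2222 lower. With library size alone 2799 were higher and 1569 lower (64.1% against 49.6% higher, median shift 0.38).

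**Figure D1:**
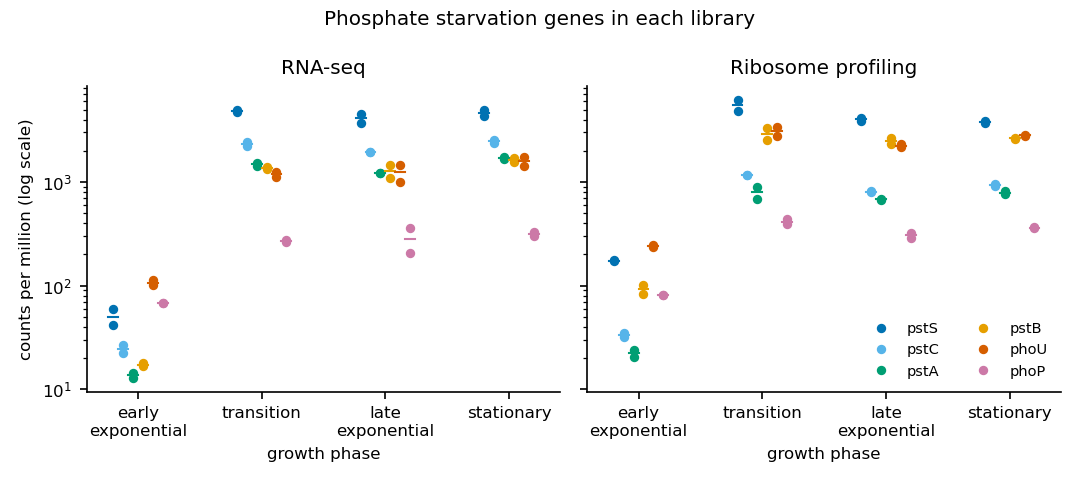
RNA-seq (left) and ribosome profiling (right) CPM, log scale, of 6 phosphate starvation genes in each library; points are libraries, bars the mean of the 2 libraries of a phase. In early-exponential phase pstS stood at 50.3 CPM of RNA and 174 CPM of footprints, and in transition phase at 4820 and 5500 CPM.

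Footprints of the phosphate transporter also rose from early-exponential to transition phase, pstA by 5.17 ± 0.18, pstC by 5.13 ± 0.16 and pstS by 4.99 ± 0.19 on the log2 scale (SE, n = 2 per phase). Footprints of pstS went from 174 ± 2.33 to 5500 ± 979 CPM (SD, n = 2). Among the other large increases were eboE (5.03 ± 0.26), asnB (4.86 ± 0.22), pqqC of pyrroloquinoline quinone synthesis (4.04 ± 0.21) and lanKC, a lanthipeptide synthetase gene (3.67 ± 0.26). Among genes with a symbol the lowest values included those of pxpB (-4.61 ± 0.50), hutU (-4.11 ± 0.19), the fructose-bisphosphatase gene glpX (-4.06 ± 0.22), dapA (CRV15_22730, -4.01 ± 0.23), hutH (-3.99 ± 0.16), ectA of ectoine synthesis (-3.90 ± 0.18) and ppdK (-3.87 ± 0.17).

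The phosphate starvation list rose in 6 of 6 members in footprints, 6 adjusted over the list alone (median 4.98; camera adjusted p = 3.79e-05; adjusted p = 0.341 with an estimated correlation). Among 8 NADH dehydrogenase genes 7 rose and 0 fell, 7 adjusted over the list alone, with nuoH at 2.68 ± 0.14 and nuoF at 2.48 ± 0.14 (camera adjusted p = 0.00048; adjusted p = 0.341 with an estimated correlation). In RNA the same list had 4 genes higher and 1 lower, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.0594). Footprints on 43 of 51 ribosomal protein genes fell and on 1 rose, the same adjusted over the list alone, with rplQ (-2.72 ± 0.19) and rpsF (-2.40 ± 0.15) lowest and rpmJ rising (0.86 ± 0.18; camera adjusted p = 2.69e-09; adjusted p = 0.371 with an estimated correlation). Of 20 synthetase genes 17 fell and 1 rose, the same adjusted over the list alone, such as lysS (-1.60 ± 0.13) and thrS (-1.57 ± 0.14; camera adjusted p = 3.79e-05; adjusted p = 0.371 with an estimated correlation). Of 11 translation factor genes 10 fell, 10 adjusted over the list alone, including lepA (-1.86 ± 0.14) and tuf (-1.59 ± 0.18; camera adjusted p = 0.000953; adjusted p = 0.371 with an estimated correlation).

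Other lists of energy metabolism fell in footprints. Of 9 genes of the cytochrome oxidase list 8 fell and 1 rose, the same adjusted over the list alone, with cydB at -3.56 ± 0.19 and cydD at -2.69 ± 0.16 (camera adjusted p = 0.000753; adjusted p = 0.341 with an estimated correlation). The 6 TCA cycle genes fell, 6 adjusted over the list alone, sdhA at -2.30 ± 0.14 and sucC at -2.28 ± 0.16 (camera adjusted p = 0.000753; adjusted p = 0.371 with an estimated correlation). The 6 arginine genes fell, 6 adjusted over the list alone, with argF at -2.03 ± 0.15 and argH at -1.81 ± 0.19 (camera adjusted p = 0.00202; adjusted p = 0.371 with an estimated correlation). Of the heat shock genes 10 of 13 fell and 1 rose, the same adjusted over the list alone, clpB at -2.03 ± 0.13 (camera adjusted p = 0.00459; adjusted p = 0.371 with an estimated correlation). Of the cell wall and division genes 13 of 21 fell and 4 rose, the same adjusted over the list alone, with murA at -1.98 ± 0.14 (camera adjusted p = 0.0324; adjusted p = 0.341 with an estimated correlation). Footprints on atpD (-1.52 ± 0.17) and sodN (-1.96 ± 0.15) fell, and those on glpK (CRV15_25075, 2.85 ± 0.18), wblA (2.24 ± 0.15), the sigma factor gene sigM (1.24 ± 0.15) and the RNA polymerase gene rpoZ (0.92 ± 0.16) rose. The copies of pyk parted, CRV15_22320 at 2.97 ± 0.20 and CRV15_06910 at -1.11 ± 0.16. Altogether 4357 of 6278 genes passed, 2227 higher and 2130 lower. Scaled by library size alone 2665 were higher and 1576 lower (62.8% against 51.1% higher, median shift 0.30).

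In late-exponential phase, footprints on pstA (4.95 ± 0.18), eboE (4.89 ± 0.26), asnB (4.77 ± 0.23), pqqB (4.61 ± 0.24), lanKC (3.94 ± 0.26) and glpK (CRV15_25075, 3.16 ± 0.18) stood above early-exponential phase (SE, n = 2 per phase). Those on ppdK (-4.83 ± 0.18), dapA (CRV15_22730, -4.77 ± 0.26), melC1 (-4.69 ± 0.27) and ectA (-4.35 ± 0.19) fell. The phosphate list rose in 6 of 6 members, 6 adjusted over the list alone (camera adjusted p = 0.000102; adjusted p = 0.376 with an estimated correlation). NADH dehydrogenase genes rose in 7 of 8 cases, 7 adjusted over the list alone, nuoF by 2.69 ± 0.15 and nuoK by 2.45 ± 0.16 (camera adjusted p = 0.00113; adjusted p = 0.376 with an estimated correlation). Ribosomal protein genes fell in 40 of 51 cases and rose in 3, the same adjusted over the list alone, with rplQ at -2.69 ± 0.19 and rpsE at -2.32 ± 0.17 (camera adjusted p = 2.9e-07; adjusted p = 0.456 with an estimated correlation). Synthetase genes fell in 17 of 20 cases and rose in 1 (2 rose adjusted over the list alone), with hisS at -1.89 ± 0.16 and thrS at -1.89 ± 0.15 (camera adjusted p = 2.15e-05; adjusted p = 0.376 with an estimated correlation). TCA cycle genes fell in 6 of 6 cases, 6 adjusted over the list alone, with sdhA at -2.83 ± 0.14 (camera adjusted p = 0.000398; adjusted p = 0.376 with an estimated correlation). Cytochrome oxidase genes fell in 8 of 9 cases and rose in 1, the same adjusted over the list alone, with cydB at -3.69 ± 0.20 (camera adjusted p = 0.000389; adjusted p = 0.376 with an estimated correlation). Also lower were lepA (-2.10 ± 0.14), clpB (-2.17 ± 0.13) and argJ (CRV15_07545, -2.19 ± 0.16). Of 6278 genes 4536 passed, 2364 higher and 2172 lower. Under library size alone 2883 were higher and 1593 lower (64.4% against 52.1% higher, median shift 0.35).

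In stationary phase the highest footprint changes among genes with a symbol included those of eboE (5.33 ± 0.25), lanKC (5.26 ± 0.26), pstA (5.16 ± 0.18), asnB (5.10 ± 0.22) and pqqB (4.78 ± 0.24; SE, n = 2 per phase). The lowest included ppdK (-4.99 ± 0.18), dapA (CRV15_22730, -4.89 ± 0.25), hutH (-4.71 ± 0.17) and pgsB (-4.08 ± 0.27). Footprints on glpK (CRV15_25075, 3.97 ± 0.18), gltB (1.53 ± 0.14) and wblA (2.20 ± 0.15) rose, and those on tpx (-2.33 ± 0.15), clpB (-1.97 ± 0.13), lepA (-2.15 ± 0.14) and qcrC of the cytochrome bc1 complex (-2.76 ± 0.13) fell. Phosphate genes rose in 6 of 6 cases, 6 adjusted over the list alone (camera adjusted p = 0.000195; adjusted p = 0.427 with an estimated correlation). NADH dehydrogenase genes rose in 7 of 8 cases, 7 adjusted over the list alone, with nuoF at 2.51 ± 0.14 and nuoH at 2.41 ± 0.14 (camera adjusted p = 0.00198; adjusted p = 0.427 with an estimated correlation). Footprints of ribosomal protein genes fell in 39 of 51 cases and rose in 1, the same adjusted over the list alone, with rplQ at -2.73 ± 0.19 and rpmF at -2.51 ± 0.14 (camera adjusted p = 1.09e-07; adjusted p = 0.478 with an estimated correlation). Synthetases fell in 17 of 20 cases and rose in 2, the same adjusted over the list alone, with trpS CRV15_09675 at -1.96 ± 0.13 and trpS CRV15_16695 at 1.12 ± 0.15 (camera adjusted p = 0.000183; adjusted p = 0.478 with an estimated correlation). The 6 TCA cycle genes fell, 6 adjusted over the list alone, with sdhA at -2.82 ± 0.14 (camera adjusted p = 0.00124; adjusted p = 0.478 with an estimated correlation). Footprints on argJ (CRV15_07545) fell (-1.27 ± 0.15), while the arginine list, with 3 of 6 lower and 3 adjusted over the list alone, did not pass (camera adjusted p = 0.159). Of 6278 genes 4713 passed, 2427 higher and 2286 lower. By library size alone 2864 were higher and 1763 lower (61.9% against 51.5% higher, median shift 0.31).

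**Figure D2:**
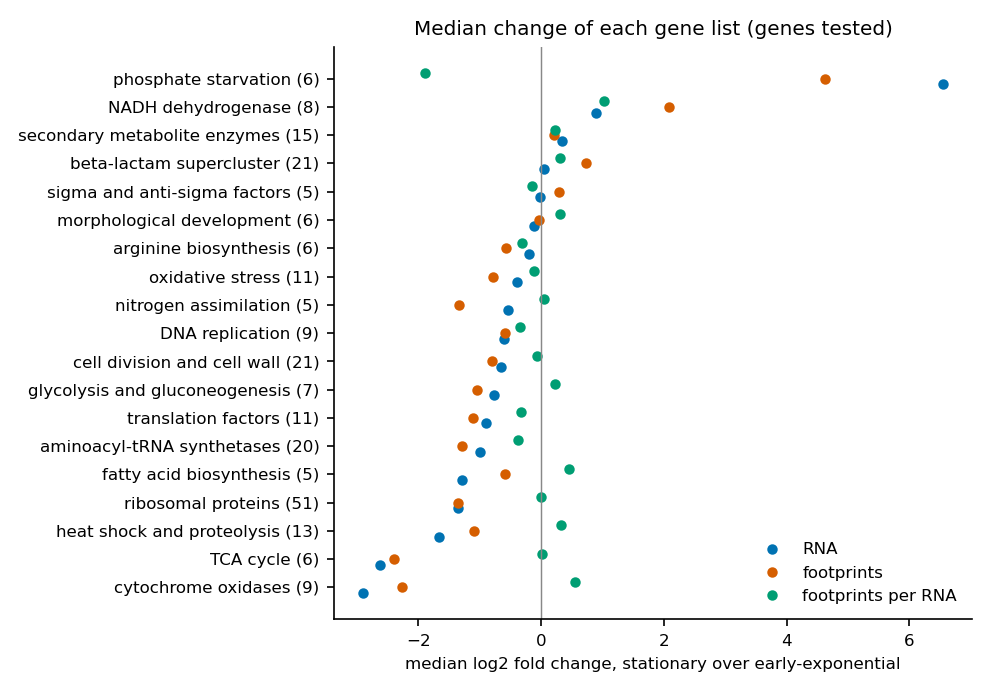
Median log2 fold change from early-exponential to stationary phase of each gene list, for RNA, footprints and footprints per RNA read; the number of genes tested in RNA is in brackets. Phosphate starvation genes stood at 6.55 in RNA, 4.62 in footprints and -1.89 in footprints per RNA read, while the TCA cycle and cytochrome oxidase lists lay lowest in RNA at -2.62 and -2.90.

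In RNA and footprints fewer genes passed between consecutive later phases than between any of these and early-exponential phase. From transition to late-exponential phase, RNA of the threonine dehydrogenase gene tdh fell by 2.48 on the log2 scale (SE 0.17, n = 2 per phase, adjusted p = 4.23e-05) and its footprints by 1.80 (SE 0.18, adjusted p = 0.000259). Footprints rose on the signal peptidase gene lepB (CRV15_05820, 1.63 ± 0.19) and on pqqB (1.14 ± 0.19). RNA of the citramalate synthase gene cimA stood 1.06 ± 0.13 higher (adjusted p = 0.00769), a call lost without transition library 1 (adjusted p = 0.0869) or 2 (adjusted p = 0.155). RNA of sbnB stood at -1.31 ± 0.18 (adjusted p = 0.00951), a call also lost without transition library 1 (adjusted p = 0.0869) or 2 (adjusted p = 0.121). Only 78 of 6567 genes passed in RNA, 39 higher and 39 lower, against 12 higher and 41 lower with library size alone (22.6% higher, median shift -0.10). That count was 7 and 2 without transition library 1 and 2, 154 and 302 without late-exponential library 1 and 2, and 29 without either stationary library. In footprints 465 of 6278 genes passed, 227 higher and 238 lower, against 144 higher and 259 lower by the DESeq2 Wald test (35.7% against 48.8% higher). The footprint count was 817 and 821 without early-exponential library 1 and 2, 195 and 241 without transition library 1 and 2, and 66 and 174 without late-exponential library 1 and 2.

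From late-exponential to stationary phase, some of the largest increases among genes with a symbol were in argJ, argB and argH of arginine biosynthesis, and gene lists were not tested in this comparison. RNA of argJ (CRV15_24250) and argB rose by 1.71 ± 0.15 and 1.64 ± 0.14 (SE, n = 2 per phase), and footprints of argB, argJ (CRV15_24250) and argH by 1.67 ± 0.17, 1.45 ± 0.16 and 1.39 ± 0.19. RNA of secD (-1.90 ± 0.23) and of the pullulanase gene pulA (-1.70 ± 0.19) fell. In RNA 344 genes passed, 169 higher and 175 lower, against 214 higher and 115 lower with library size alone (65% against 49.1% higher, median shift 0.11). The RNA count was 229 without transition library 2, 649 without late-exponential library 2, and 92 and 100 without stationary library 1 and 2. In footprints 347 genes passed, 258 higher and 89 lower. The footprint count was 569 and 574 without early-exponential library 1 and 2, 150 and 145 without late-exponential library 1 and 2, and 176 and 121 without stationary library 1 and 2.

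From early-exponential to transition phase, the transporter genes pstS (-1.68 ± 0.25), pstA (-1.68 ± 0.23), pstC (-1.52 ± 0.20) and pstB (-1.42 ± 0.25) fell in translation efficiency although their footprints rose (log2 change, SE, n = 2 libraries per phase and assay). The tyrosine degradation gene hppD (2.26 ± 0.38), the DNA glycosylase gene mug (2.17 ± 0.32), galT of galactose use (2.14 ± 0.36), the membrane protease gene htpX (CRV15_10455, 2.04 ± 0.22), sbnA (1.98 ± 0.25) and sbnB (1.77 ± 0.22) of diaminopropionate synthesis, and tpg, a terminal protein gene of linear replicons (1.87 ± 0.26), rose. Ribosomal protein genes went both ways: rpmJ (1.41 ± 0.27) and rpsR (1.13 ± 0.23) rose while rpmG (-2.06 ± 0.37) and rplQ (-1.29 ± 0.26) fell. The ribosome silencing factor gene rsfS (-1.36 ± 0.19) and the synthetase genes aspS (-1.23 ± 0.21) and argS (-0.86 ± 0.19) fell, as did lepA (-0.87 ± 0.19). Here and below aspS is CRV15_13110, and CRV15_13450 carries the same symbol. The genes ctaE (0.99 ± 0.23), sigM (1.16 ± 0.21) and the division gene ftsW (1.08 ± 0.19) rose.

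Of the 6 phosphate genes 4 fell in translation efficiency, 4 adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.535 with an estimated correlation). Of 8 NADH dehydrogenase genes 4 rose, 7 adjusted over the list alone (median 1.22; camera adjusted p = 0.000696; adjusted p = 0.535 with an estimated correlation). Of 9 cytochrome oxidase genes 3 rose, 3 adjusted over the list alone (camera adjusted p = 0.00409; adjusted p = 0.535 with an estimated correlation). Of 20 synthetase genes 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.0083; adjusted p = 0.702 with an estimated correlation). In total 971 of 6211 genes passed the interaction test, 521 higher and 450 lower. The count was 545 without transition RNA library 1, 625 without transition RNA library 2 and 510 without transition ribosome profiling library 1.

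In late-exponential phase translation efficiency was higher than in early-exponential phase for tpg (2.47 ± 0.26), lepB (CRV15_05820, 2.31 ± 0.27), sbnA (2.21 ± 0.29), mug (2.19 ± 0.33), htpX (CRV15_10455, 2.13 ± 0.22), tgmB (1.40 ± 0.22) and ftsW (1.36 ± 0.19; SE, n = 2 per phase and assay). It fell for rpmG (-2.41 ± 0.37), pstS (-1.93 ± 0.25), pstC (-1.85 ± 0.20), rpmF (-1.79 ± 0.25), rplQ (-1.74 ± 0.26), the gyrase gene gyrB (-1.09 ± 0.21) and the thioredoxin reductase gene trxB (-1.09 ± 0.19). Of 20 synthetase genes 10 fell, 11 adjusted over the list alone, with aspS at -1.29 ± 0.22 (camera adjusted p = 1.42e-05; adjusted p = 0.628 with an estimated correlation). Of 11 translation factor genes 7 fell, 7 adjusted over the list alone, with lepA at -0.98 ± 0.19 (camera adjusted p = 0.00139; adjusted p = 0.628 with an estimated correlation). Of 51 ribosomal protein genes 13 fell and 4 rose, 19 and 4 adjusted over the list alone (camera adjusted p = 0.000903; adjusted p = 0.714 with an estimated correlation). Of 9 DNA replication genes 5 fell, 5 adjusted over the list alone (camera adjusted p = 0.000903; adjusted p = 0.362 with an estimated correlation). The phosphate list fell in 4 of 6 members, 4 adjusted over the list alone (camera adjusted p = 4.15e-05; adjusted p = 0.362 with an estimated correlation). The NADH dehydrogenase list rose in 3 of 8 members, 6 adjusted over the list alone, nuoF rising by 1.44 ± 0.32 (camera adjusted p = 0.00158; adjusted p = 0.628 with an estimated correlation). Of 6211 genes 1080 passed, 499 higher and 581 lower, against 735 higher and 309 lower with library size alone (70.4% against 46.2% higher, median shift 0.20). Only 674 passed without late-exponential ribosome profiling library 1.

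In stationary phase the phosphate transporter genes fell in translation efficiency, pstS at -2.17 ± 0.25, pstC at -1.97 ± 0.20, pstA at -1.92 ± 0.23 and pstB at -1.86 ± 0.25 (SE, n = 2 per phase and assay). The list fell in 4 of 6 members, 4 adjusted over the list alone (camera adjusted p = 0.000108; adjusted p = 0.563 with an estimated correlation). Its other members, phoU (-0.43 ± 0.24) and phoP (-0.16 ± 0.26), which were chosen after their values were seen, did not pass. Single genes that fell were rpmG (-2.49 ± 0.37), ribD of riboflavin synthesis (-2.47 ± 0.29) and thiO of thiamine synthesis (-1.87 ± 0.26). Increases were seen in sbnA (2.28 ± 0.28), mug (2.21 ± 0.32), htpX (CRV15_10455, 2.02 ± 0.22), tpg (2.01 ± 0.26), hppD (1.75 ± 0.38), tgmB (1.31 ± 0.22), glnA (1.27 ± 0.24), rpmJ (1.14 ± 0.27) and htpG (1.08 ± 0.21). Synthetase genes fell in 5 of 20 cases, 5 adjusted over the list alone, with aspS at -1.63 ± 0.21 and serS at -1.16 ± 0.19 (camera adjusted p = 0.0021; adjusted p = 0.695 with an estimated correlation). The factor gene lepA fell (-1.10 ± 0.19). NADH dehydrogenase genes rose in 2 of 8 cases, 4 adjusted over the list alone (camera adjusted p = 0.0176; adjusted p = 0.695 with an estimated correlation). Cytochrome oxidase genes rose in 2 of 9 cases, 4 adjusted over the list alone (camera adjusted p = 0.0421, 0.0528 with the cell sample as a block; adjusted p = 0.589 with an estimated correlation). In total 1411 of 6211 genes passed, 704 higher and 707 lower. Only 890 passed without stationary ribosome profiling library 2.

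Changes of RNA and of footprints against early-exponential phase followed each other across genes. Over 6211 genes, which are not independent replicates, Pearson r of the log2 fold changes was 0.86 in transition, 0.87 in late-exponential and 0.88 in stationary phase. Spearman rho was 0.85, 0.86 and 0.87, and the total-least-squares slope was 1.02 in each. RNA and footprints passed their tests in the same direction in 1554 genes higher and 1632 lower in transition phase, 1665 and 1669 in late-exponential phase, and 1789 and 1798 in stationary phase. By the labels both assays came from the same cell samples, so a shared effect of the culture may be part of these values. The authors' deposited table of fold changes, made on a second count of the libraries, correlated across 6265 genes at r = 0.991, 0.989 and 0.991 with the RNA changes computed here for the 3 phases against early-exponential phase. The footprint changes correlated across 6054 genes at 0.978, 0.977 and 0.978. Between consecutive later phases r was lower, 0.929 and 0.934 in RNA and 0.931 and 0.916 in footprints. Of the genes called here in RNA, 3873 of 3873, 3958 of 3958 and 4241 of 4243 had the same sign in the authors' deposited table in the 3 phases against early-exponential phase. Of those called in footprints, 4212 of 4238, 4368 of 4396 and 4530 of 4563 did. From transition to late-exponential and on to stationary phase, 75 of 75 and 335 of 335 did in RNA and 442 of 444 and 341 of 341 in footprints.

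The genes of cephamycin C and clavulanic acid synthesis lie side by side on the chromosome. The region taken here lies between the outermost genes matched by symbol, so genes of the same cluster may lie beyond it. It runs from the beta-lactamase gene bla to the clavaminate synthase gene cs1, chromosome 1860925 to 1901283 of assembly ASM551946v1, and holds 21 genes. In transition phase its footprints rose in 16 genes and fell in 1, the same adjusted over the list alone (median 0.85; camera adjusted p = 0.00231; adjusted p = 0.411 with an estimated correlation). In RNA 7 rose and 2 fell, the same adjusted over the list alone (median -0.02; camera adjusted p = 0.506). RNA of cs1 (CRV15_07540) rose by 1.23 ± 0.19, with 3550 ± 958 CPM in early-exponential and 8310 ± 391 CPM in transition phase (SD, n = 2), and its footprints rose by 2.05 ± 0.16. Also higher in RNA were CRV15_07495 (1.21 ± 0.17), CRV15_07515 (0.99 ± 0.19), CRV15_07490 (0.90 ± 0.16) and the agmatinase-family gene speB (0.82 ± 0.19), and CRV15_07445 (-1.54 ± 0.16) and CRV15_07450 (-0.83 ± 0.14) were lower. Footprints rose on CRV15_07490 (2.32 ± 0.17), cs1, CRV15_07500 (1.72 ± 0.13), CRV15_07515 (1.54 ± 0.17), CRV15_07460 (1.23 ± 0.19) and CRV15_07470 (1.11 ± 0.20), and fell on CRV15_07445 (-1.35 ± 0.13). Other footprint changes were 1.08 ± 0.17 for CRV15_07495, 0.87 ± 0.14 for CRV15_07530, 0.86 ± 0.17 for speB and 0.85 ± 0.18 for CRV15_07525.

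The first cephamycin step, lysine aminotransferase (lat), had RNA at -0.16 ± 0.16 in transition and -0.07 ± 0.16 in late-exponential phase, neither past the test. In stationary phase lat stood at 0.19 ± 0.16 in RNA (adjusted p = 0.304), and with library size alone at 0.56 (adjusted p = 0.00175). Footprints on lat rose by 0.73 ± 0.14 in late-exponential and by 0.84 ± 0.14 in stationary phase. The carbamoyltransferase gene cmcH had RNA at -0.23 ± 0.19 (adjusted p = 0.306) and footprints at 0.48 ± 0.16 (adjusted p = 0.0147) in transition phase, a footprint call lost without early-exponential library 2 (0.38, adjusted p = 0.0868) or transition library 1 (0.35, adjusted p = 0.0766). For bla the libraries held only 1.66 to 5.07 CPM of RNA and 2.17 to 14.8 CPM of footprints. The second gene named cs1, CRV15_13885 outside the region, had a mean of 10 CPM of RNA with 0.11 ± 0.33 (adjusted p = 0.782) in transition phase. Its footprints stood at 0.36 ± 0.25 (adjusted p = 0.206), and at 0.65 with library size alone (adjusted p = 0.0391).

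Translation efficiency in the region rose in 7 of 21 genes and fell in 1 in transition phase, the same adjusted over the list alone (median 0.48; camera adjusted p = 0.000165; adjusted p = 0.535 with an estimated correlation). CRV15_07490 (1.33 ± 0.23), CRV15_07470 (1.21 ± 0.28), CRV15_07500 (1.10 ± 0.23), CRV15_07450 (1.07 ± 0.20) and CRV15_07475 (1.06 ± 0.21) rose, the RNA of CRV15_07470 (-0.18 ± 0.17) and CRV15_07475 (-0.16 ± 0.17) not passing the test. In late-exponential phase translation efficiency rose in 8 genes and fell in 0, the same adjusted over the list alone (median 0.46; camera adjusted p = 0.000811; adjusted p = 0.65 with an estimated correlation), with CRV15_07530 at 1.08 ± 0.23. In stationary phase it rose in 6 genes and fell in 0, 7 and 1 adjusted over the list alone (median 0.31; camera adjusted p = 0.032, 0.0574 with the cell sample as a block; adjusted p = 0.736 with an estimated correlation), with CRV15_07490 at 1.32 ± 0.23. Footprints of the region rose in 13 genes and fell in 2 in late-exponential phase, the same adjusted over the list alone (camera adjusted p = 0.0374; adjusted p = 0.533 with an estimated correlation). In stationary phase 13 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.0419; adjusted p = 0.513 with an estimated correlation). RNA of cs1 stood at 1.22 ± 0.19 and 1.36 ± 0.19, and CRV15_07445 at -1.47 ± 0.16 and -1.65 ± 0.16, in late-exponential and stationary phase.

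**Figure D3:**
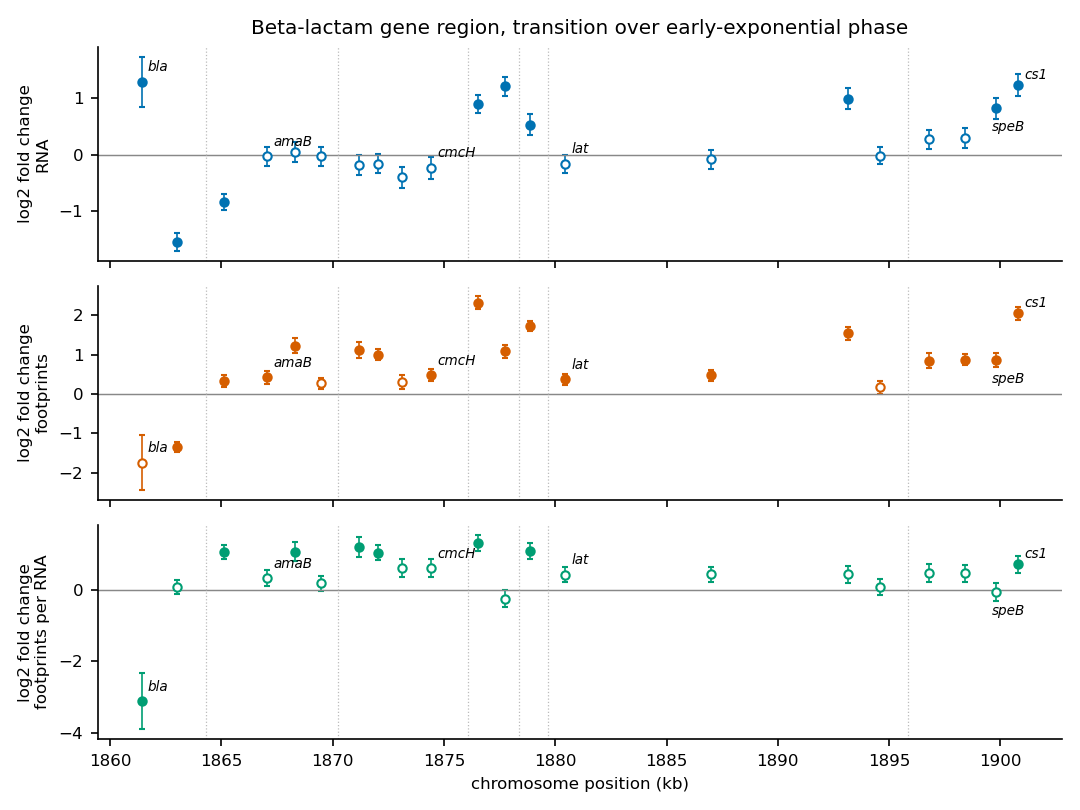
Log2 fold change from early-exponential to transition phase (vertical axes, with SE bars) of RNA, footprints and footprints per RNA read for the 21 genes from bla to cs1, at their chromosome position in kb; filled points passed the test and dotted lines mark listed start sites. Footprints rose in 16 of the 21 genes and RNA in 7, and bla, at 1.66 to 5.07 CPM of RNA, carries the widest errors.

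The authors' list of transcription start sites, made from the pooled libraries, held 2659 sites, 2203 on the chromosome and 456 on the plasmid. Of these 1901 carried the class letter P, 264 S, 264 A and 75 N, the rest being I. Sites of class A, I and N were left out of the distances below. Among them were 152 sites of class I with gene coordinates, at a median distance of -9 nt, which is past the start codon. For 2101 sites of class P and S within 500 nt upstream, the distance to the start codon of the named gene was taken. Its median was 57 nt (95% interval 54 to 61), with quartiles of 26 and 132 nt, and 703 sites (33.5%) lay over 100 nt away. Of these 2101 sites, 451 (21.5%, 95% Wilson interval 19.8 to 23.3%) lay under 9 nt from the start codon and gave leaderless transcripts, and 423 (20.1%) lay on it. The leaderless share was 21.6% on the chromosome (390 of 1805) and 20.6% on the plasmid (61 of 296), which Fisher's exact test did not separate (two-sided p = 0.76). In the beta-lactam region, sites lay 275 nt upstream of CRV15_07445, 83 nt upstream of lat and 51 nt upstream of CRV15_07525, and pstS had a site at 107 nt.

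**Figure D4:**
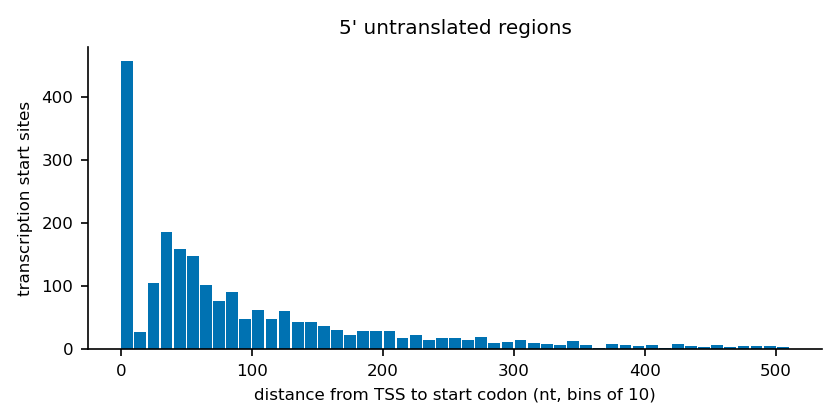
Number of transcription start sites (vertical axis) by distance to the start codon in bins of 10 nt, for 2101 sites of class P and S within 500 nt upstream. The first bin holds 456 sites, the next 27, and the highest count beyond it is 185 at 30 to 39 nt.

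Leaderless genes had lower RNA levels, with a median of 55.3 CPM against 105 CPM for genes with a leader, a difference of -0.93 in median log2 CPM (permutation test across genes, added after the medians were seen, p = 1.0e-05, the smallest that 100000 resamples allow). Averaged over the phases, their translation efficiency did not differ detectably. The median log2 ratio of footprints to RNA was 0.09 over 451 leaderless genes and 0.19 over 1390 others, a difference of -0.10 (two-sided permutation test across genes, which are not independent replicates, 100000 resamples, p = 0.132). By phase, in tests added after the medians were seen and adjusted over 7 tests, leaderless and other genes stood at 0.20 and 0.18 in early-exponential (permutation test, adjusted p = 0.812), 0.11 and 0.20 in transition (adjusted p = 0.261), 0.06 and 0.08 in late-exponential (adjusted p = 0.725) and -0.02 and 0.23 in stationary phase (adjusted p = 9.3e-04). The change from early-exponential phase was lower for leaderless than for other genes by 0.22 in stationary phase, at -0.16 against 0.06, and by 0.17 in transition phase, at -0.13 against 0.04 (permutation test, adjusted p = 3.5e-05 for each). In late-exponential phase the changes were -0.16 and -0.11 (permutation test, adjusted p = 0.261). Whether the lower RNA level of leaderless genes accounts for these differences was not tested. The leaderless genes with most footprints were CRV15_10680 (chromosome 2601155 to 2602042), with 2180 CPM of footprints, 2990 CPM of RNA and a log2 ratio of -0.25, CRV15_16875 (3999901 to 4000740), with 1980 and 1390 CPM and 0.65, and CRV15_19525 (4635778 to 4636956), with 1420 and 2360 CPM and -0.54.

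Genes of the linear plasmid took a larger share of reads in the later phases than in early-exponential phase, with the highest share in transition phase. The share of RNA counts on the plasmid was 4.58 ± 0.01% in early-exponential, 8.59 ± 0.08% in transition, 7.47 ± 0.57% in late-exponential and 7.65 ± 0.15% in stationary phase (SD, n = 2). Of footprints it was 4.31 ± 0.20%, 8.29 ± 0.20%, 7.63 ± 0.05% and 7.83 ± 0.11%. An exact permutation test over the 4 phases, added after the shares were seen, gave p = 0.0286 for RNA and p = 0.00952 for footprints, the smallest p that its 105 arrangements allow. In transition phase 508 plasmid genes of 1237 tested rose in RNA and 236 fell (median log2 fold change 0.53), against 1403 and 1772 of 5111 chromosomal genes (median -0.07).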

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

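In this part, the tests of library scaling, the counts under other scalings and the bootstrap interval were chosen after the result was seen. The genes that follow the beta-lactam region were also added after the data were seen, and the other tests were chosen before. In transition phase 55 genes had RNA and footprints that changed in opposite directions against early-exponential phase, each past its test and with the difference between assays past the interaction test. In late-exponential phase there were 79 such genes and in stationary phase 105. The interaction test removed no gene in these phases and adds no support, since opposite changes past both tests nearly fix its outcome. RNA was the lower of the pair in 44, 57 and 68 of the 55, 79 and 105 genes. These counts depend on the scaling: with library size alone there were 38, 86 and 92 such genes, RNA lower in 26, 62 and 49, and with DESeq2 size factors 55, 82 and 105, RNA lower in 40, 49 and 60. One with a symbol was htpX (CRV15_10455, chromosome 2547216 to 2548076), a membrane protease gene. Its RNA fell from 276 ± 23.8 to 173 ± 7.31 CPM (SD, n = 2) from early-exponential to transition phase, while its footprints rose from 307 ± 42.1 to 837 ± 97.0 CPM. As log2 fold changes, chosen after their values were seen, these were -0.68 (adjusted p = 0.00139) and 1.45 (adjusted p = 1.18e-06). With library size alone the RNA change of htpX was -0.32 and not past the test (adjusted p = 0.0804). The DNA glycosylase gene mug stood at -1.27 in RNA and 0.99 in footprints in transition phase, lepB (CRV15_05820) at -0.52 and 1.90 in late-exponential phase, and aspS (CRV15_13110) at 0.45 and -1.07 in stationary phase, all chosen after their values were seen.

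The second deposited count, on RefSeq tags, held 482 genes that the annotation did not link to a gene of the first count. Of these, 141 had over 3 reads in every library, above what a count of 0 allows, and together the 482 took 0.64 to 1.05% of the RNA reads and 1.18 to 2.12% of the footprints of that count. The first count in turn held 398 genes without an annotation entry, with 0.464 to 0.824% of its RNA counts and 0.885 to 1.56% of its footprints. Some of the 482 may therefore be the same genes under another tag. The largest of the 482 was CRV15_RS13905, for which no symbol is given. Its footprints stood at 6210 ± 976 CPM in early-exponential, 9180 ± 1160 in transition, 10600 ± 134 in late-exponential and 8110 ± 437 in stationary phase, against 652 ± 27.2, 640 ± 35.7, 1020 ± 373 and 983 ± 138 CPM of RNA (SD, n = 2), all by library total without TMM factors. These differences were not tested.

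The drop of footprints per RNA read of the phosphate genes from early-exponential to stationary phase had a median of -1.89 on the log2 scale. With library sizes alone it was -1.84, but that setting moved the median of all genes by only 0.04, so it did not test scaling. A scale factor moves all genes of a library alike, while the median change of all genes was -0.008. These values argue against scaling as the reason why the phosphate genes fell relative to other genes. If background raised the footprints of weakly transcribed genes, other genes at the same early-exponential RNA level, 13.7 to 107 CPM, would share the high ratio. Of these, the 748 genes whose RNA change to stationary phase did not pass the test were taken. Their median log2 ratio was 0.05 (quartiles -0.87 and 0.74) against 1.18 for the phosphate genes (0.52 to 2.67), but the 95% bootstrap interval of the difference, 0.57 to 2.30, reached below the bound of 1 set before, so background stayed open. The interval treats the phosphate genes as independent, although the pst genes are neighbours. A lag of footprints behind any steep RNA rise stayed open too: 289 other genes whose RNA rose at least 8-fold in the libraries numbered 1 had a median change of -0.66 in those numbered 2 (quartiles -1.50 and 0.15), against -1.81 for the phosphate genes.

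The gain of footprints per RNA read in the beta-lactam region in transition phase had a median of 0.48. It lay between 0.38 and 0.66 when any of the 16 libraries was left out, so no 1 library made it. Of 4933 windows of 21 consecutive chromosomal genes, 1.86% had a median as high, so most neighbourhoods did not move together this far. The gain in this ratio was not limited to the stretch from bla to cs1: the 14 genes that follow it had a median of 0.53, with 6 higher and 0 lower, 7 and 0 adjusted over the list alone. RNA fell in most of these 14 genes, as given below, while from bla to cs1 more genes rose than fell in RNA. The ratio alone does not show whether footprints of the 14 genes rose. The ends of that stretch were set by matched gene symbols, so the 14 genes may belong to the same gene cluster. With library sizes alone or DESeq2 size factors the median of the region was at least 0.49. These settings moved the median of all genes by at most 0.03, so they did not test scaling. A scale factor moves all genes of a library alike and cannot set the region apart from the median of all genes, -0.04. The set test rests on the preset correlation.

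The plasmid share of RNA reads was 1.87 times as high in transition as in early-exponential phase. Without the 10 plasmid genes with most reads, which held 22.9% of the plasmid reads, the ratio was 1.69, so a few genes did not make the rise. More plasmid copies per cell would raise most plasmid genes. Their median log2 fold change lay 0.59 above that of chromosomal genes and 66.3% lay above the chromosomal median, which could not tell copy number from regulation, and no DNA was measured.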

How the results depend on the processing

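No named gene that passed its test turned direction under any setting, while library size alone turned the balance of higher and lower calls to more higher ones in 7 comparisons. These were RNA in transition (2650 and 1329), late-exponential (2425 and 1599) and stationary phase (2799 and 1569) and from late-exponential to stationary phase (214 and 115), footprints from transition to late-exponential phase (206 and 168), and translation efficiency in late-exponential (735 and 309) and stationary phase (703 and 557). Of 5472 values of named genes under other settings, 5441 stayed called or not called as in the main fit, 29 lost a call and 2 gained one. Of the 29, 22 were lost to the required fold of at least 2. The named results, 298 of 306 called in the main fit, were mostly chosen as the highest and lowest calls. Their stability was thus largely set by that choice and says little about the other calls. Over 7 other settings the calls against early-exponential phase ranged from 3744 to 4157 for RNA in transition, 3694 to 4107 in late-exponential and 4156 to 4532 in stationary phase, and for footprints from 4018 to 4360, 4242 to 4563 and 4426 to 4763. With a fold of at least 2 also required, which allows fewer genes by construction, 2536 and 2710 RNA calls were left in transition and late-exponential phase, 39 between transition and late-exponential and 161 between late-exponential and stationary phase. For footprints 2858 were left in transition phase, 102 and 112 between later phases, and for translation efficiency 539, 604 and 770. From transition to late-exponential phase the RNA calls numbered 163 by the DESeq2 Wald test, 39 with only the 2 phases compared and 46 on the RefSeq recount, and footprint calls from late-exponential to stationary phase 830 with only the 2 phases compared; the cause was not tested. Leaving out 1 library gave 2 to 302 and 92 to 649 RNA calls and 66 to 821 and 121 to 574 footprint calls between later phases, and 510 to 1134, 674 to 1208 and 890 to 1627 translation efficiency calls; the cause was not tested. The median distance of start sites was 53 nt in a window of 300 nt and 49 nt with the nearest site per gene, which raised the leaderless share to 24.4%. Protein-coding genes alone gave a plasmid share of 4.608% of RNA in early-exponential and 7.745% of footprints in late-exponential phase. At 50 CPM or more, r of RNA and footprint changes was 0.91 in each of the 3 phases. Leaderless genes at that level, averaged over phases, differed by -0.08 (permutation p = 0.317).

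The 171 list tests include those that did not pass. With the estimated correlation 76 lost their call, and no list printed in this report as passing kept it. With library size alone 4 lost and 4 gained it, and with DESeq2 factors 1 lost it. The replicate number does not pair the phases by the labels: same-numbered libraries deviated together at -0.11 to 0.00 in RNA and -0.22 to 0.10 in footprints. With it as a replicate block, RNA calls numbered 3948, 4035, 4361, 55 and 296 and footprint calls 4309, 4508, 4692, 453 and 333, in the order of the report, and footprints of the DNA replication list in late-exponential phase (1 of 9 rose, 6 fell, 1 and 7 adjusted over the list alone; camera adjusted p = 0.0499) had adjusted p = 0.055, and adjusted p = 0.376 with an estimated correlation. The cell sample as a block gave 1037, 1163 and 1508 translation efficiency calls and changed no other call than those given. Depth limits calls on weak genes: 3 counts are up to 0.646 CPM of RNA by library total.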

Other observations

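The tests of symbol families below were chosen after the data were seen, and the test of offsetting changes before, apart from its opposite pairing of libraries. The genes of pyrroloquinoline quinone synthesis, a redox cofactor, rose from early-exponential to transition phase in RNA in 5 of 5 cases, 5 adjusted over the list alone (median 3.09; camera adjusted p = 0.0048; adjusted p = 0.382 with an estimated correlation). Their footprints rose in 5 of 5 cases as well, 5 adjusted over the list alone (median 3.31; camera adjusted p = 0.0177; adjusted p = 0.446 with an estimated correlation). Among 10 CRISPR-associated cas genes 6 rose in RNA and 0 fell, 6 adjusted over the list alone (median 1.62; camera adjusted p = 0.0244, 0.0809 with library size alone; adjusted p = 0.382 with an estimated correlation). The 4 sbn genes, named for a siderophore of Staphylococcus, all fell in RNA, 4 adjusted over the list alone (median -2.53; camera adjusted p = 0.00746; adjusted p = 0.37 with an estimated correlation). Of 10 hem genes of heme synthesis 9 fell and 1 rose, the same adjusted over the list alone (median -1.08; camera adjusted p = 0.00734; adjusted p = 0.37 with an estimated correlation). Of 7 dap genes of lysine and cell wall precursor synthesis 6 fell, 6 adjusted over the list alone (median -1.68; camera adjusted p = 0.0048; adjusted p = 0.37 with an estimated correlation).

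Beside the transporter, the phosphate regulator genes phoU (CRV15_12395) and phoP (CRV15_12385), chosen after their values were seen, rose in RNA in transition phase by 3.47 ± 0.21 and 1.99 ± 0.22 on the log2 scale (SE, n = 2 per phase). Start sites lay 187 and 53 nt upstream of phoU. The 14 genes that follow the beta-lactam region, chromosome 1901284 to 1921313, had RNA lower in 10 and higher in 0 in transition phase, the same adjusted over the list alone (median -0.74), and translation efficiency higher in 6 and lower in 0, 7 and 0 adjusted over the list alone (median 0.53). Across 1879 genes the deposited score of class P sites had a Spearman rho of 0.44 with RNA CPM.

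Whether changes in translation efficiency offset changes in RNA was tested across 6211 genes from early-exponential to stationary phase. To keep the RNA count from entering both values, the RNA change of libraries numbered 1 was set against the translation efficiency change of libraries numbered 2. Pearson r was -0.24, past the level of -0.1 set beforehand for this pairing. The opposite pairing, which was not part of the rule set beforehand, gave -0.02, so the data could not tell. In transition phase the pairings gave -0.28 and 0.01.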
